A study of Homo sapiens with 8 samples.

How the data were processed

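The series measured gene expression in PC-3 cells, a human prostate cancer cell line, on Clariom D microarrays. The 8 arrays form 4 groups of 2: control, calcitriol at 10 nM, TGF-β1 at 5 ng/mL, and both agents together, with 24 h of treatment per the labels' protocols. The labels give no incubation time and no vehicle for the controls. They state independent experiments for each condition, so n = 2 counts experiments and not repeat scans. Groups were taken from the sample titles.

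The values used are the deposited log2 expression values, 1 per feature and array, for 138745 features. RMA, oligo and limma are named in the submitters' processing notes without versions, and log2 is taken as the base because it is the usual RMA output. The order of normalization steps and the genome build are not given in the sources used here, so no coordinates are printed. Median values per array lay between 4.33 and 4.35, and 75th percentiles between 5.77 and 5.78, so the arrays had been brought to a common scale before deposit. No raw scanner file was used here.

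Features were named through the platform's list of probes. It gave exactly 1 symbol for 36176 features and several for 1119, and 98455 were not listed and are unnamed here. Another 2995 features are controls of the array itself, among them 612 negative and 2197 positive control features. The Entrez identifiers of 25516 features matched the reference genes, and 0 symbols changed when updated through it. Some genes of the fixed lists have no feature in that list and were not analysed here.

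The following choices were made before the data were examined. Features above 4.34, the 50th percentile of all values, in at least 2 arrays were kept, and for each gene the feature with the highest mean over the 8 arrays was used. This left 23854 genes, 71.0% of the 33616 with a symbol, of which 14793 are protein-coding and 5862 are pseudogenes. A linear model with 1 mean per group was fitted to all 8 arrays in limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table) with empirical Bayes moderation and 4 residual degrees of freedom. There were 6 contrasts: each treatment against control, the combination against each single agent, and the interaction, which is 0 where log2 effects add up. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg over the genes of a contrast, and genes with an adjusted p under 0.05 are described as changed, higher or lower.

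At the same time 33 gene lists holding 675 genes were fixed, and 558 of these genes were tested. The 32 lists with at least 5 tested members entered limma's camera test, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and with adjustment over the lists of a contrast. The same test with an estimated correlation was an alternative, as was limma's fry, which tests whether the genes of a list move, on balance, one way and does not compare them with other genes. The mitochondrial list had 1 tested member and was left out. Counts of list members that changed are given both over all genes and after adjustment over the list alone.

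The genes named in the text follow a rule set at the same time. For each treatment against control it takes the 6 largest rises and falls among changed genes with both treated arrays outside the range of the controls, up to 4 changed members of each list, and 5 treatment checks, 4 of which were tested. For the other contrasts it takes 5 rises and 5 falls, or the 5 lowest p-values where nothing passed. Pseudogenes and unnamed loci are not named. List members named beyond the first 4, or because they passed over the list alone, were chosen after their values were seen, and other genes outside the rule are marked so.

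The 95th percentile of the negative control features of each array served as background. Where every array of a group lay at or under it, the fold is given as a lower bound against that background, and no fold is given where both groups lay under it or where that bound is under 1. Where only some arrays of a group lay above it, their number is given, and where that is the lower group, levels replace the fold. Comparisons that share the controls were set against 100 simulated data sets in which no gene changed, drawn with the moderated spread pooled over all groups. Exact permutation of group labels cannot reach a p of 0.05 with 2 arrays per group, and groups of 2 allow no test for outlying arrays. The number of arrays limits the precision of every value.

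The pipeline was tested on simulated data in which 200 of 23854 genes changed, 50 at each fold size. Genes kept their measured mean levels and were drawn independently, with the moderated spread of each gene taken as its true spread. Genes that vary together or vary more than this were not simulated, so the rates that follow may be optimistic. Recovery of 1.5-fold changes was 16% for calcitriol, 18% for TGF-β1 and 22% for the combination against control, 24% for the combination against either single agent and 4% for the interaction. Recovery of 2-fold changes was 100%, 90%, 92%, 98% (against calcitriol), 88% (against TGF-β1) and 52% (interaction). In the same runs, 3 of 161 calls were of unchanged genes for calcitriol, 4 of 158 for TGF-β1, 5 of 162 for the combination, 9 of 170 against calcitriol, 7 of 163 against TGF-β1 and 11 of 137 for the interaction. A simulated list of 25 genes shifted by 0.3 in the TGF-β1 contrast was found, with a camera adjusted p of 6.1e-20. Of the other lists of that set of 20, 0 were called. These lists also held independent genes, so this does not show how lists of genes that vary together behave.

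Alternatives covered the filter on low values, the feature chosen per gene, repeated normalization, the variance model, array weights, a fit of the compared groups only, thresholds, a term for the replicate letter and the omission of each array. Chosen after seeing the data were cyclic loess between arrays over all features, an analysis of protein-coding genes alone, cyclic loess over protein-coding genes, and 1 control array for each of the comparisons that share the controls. Plots were drawn with matplotlib 3.10.9.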

Results

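PC-3 cells were given neither agent, or were exposed for 24 h to calcitriol (10 nM), to TGF-β1 (5 ng/mL) or to both. Calcitriol is the active form of vitamin D, and TGF-β1 is a growth factor that signals through SMAD proteins. The series asks how the joint treatment acts on tumour-related pathways in these cells. There were 2 arrays per group, each with deposited log2 values for 138745 features. Array medians lay between 4.33 and 4.35. Replicates of a group correlated at r = 0.988 to 0.991 across genes, and arrays of different groups at 0.977 to 0.990. The gap between the positive and the negative control features of the array, a measure of signal over background, was 7.03 ± 0.015 in control, 6.98 ± 0.064 with calcitriol, 6.93 ± 0.025 with TGF-β1 and 6.74 ± 0.051 with both (log2, SD, n = 2).

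The first comparison asks what calcitriol alone does. CYP24A1, the enzyme that inactivates calcitriol, rose 21.9-fold, from a mean log2 level of 5.49 to 9.95 (log2 change 4.46 ± 0.35, SE, n = 2 per group, adjusted p = 0.0247). IGFBP3, which encodes a binding protein for insulin-like growth factors, rose 3.11-fold (1.64 ± 0.11, adjusted p = 0.0153). These were the 2 genes of 23854 that changed, both higher. Among the 26 vitamin D receptor target genes tested, 2 rose over all genes, and 5 rose when adjusted over the list alone: CYP24A1, IGFBP3, EFL1 (1.30), SERPINB1 (0.71) and KLK6 (0.64). EFL1, a ribosome assembly factor with a near-identical copy, had an adjusted p of 0.0672 over all genes. This was the only list of 32 that was shifted (camera adjusted p = 0.00565, median log2 change 0.06, mean 0.33), with an adjusted p = 0.441 with an estimated correlation. VDR, the receptor itself, stood at 9.52 in control and 9.22 with calcitriol (-0.30 ± 0.10, adjusted p = 0.636). The TGF-β targets SMAD7 (0.12, adjusted p = 0.86) and PMEPA1 (-0.30, adjusted p = 0.655) did not pass. At an unadjusted p under 0.05 there were 1752 genes, against 1192.7 by chance. Without any 1 of the calcitriol, control or TGF-β1 arrays 0 genes passed in limma, and without either combination array 2 passed.

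**Figure D1:**
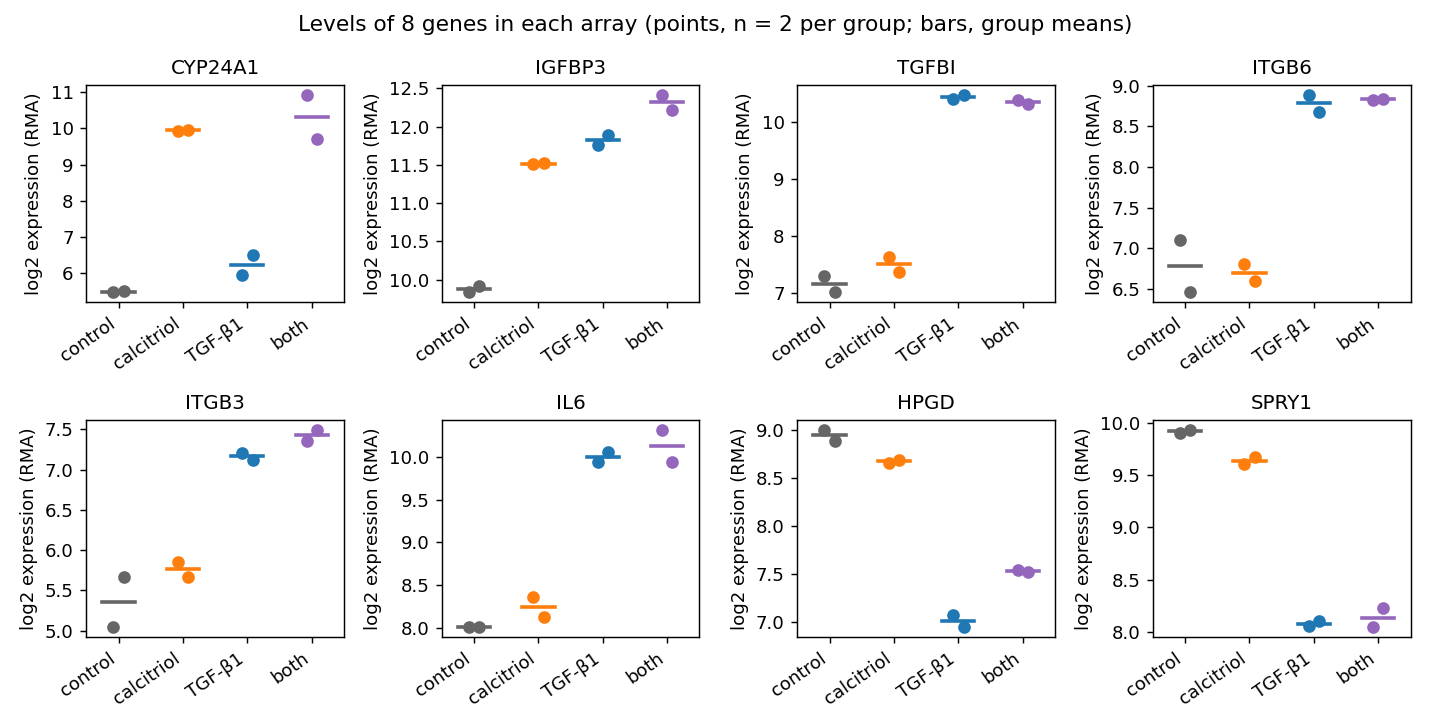
Log2 expression (RMA) of 8 genes in each array; points are the 2 arrays of a group and bars are group means. CYP24A1 averaged 5.49 in control, 9.95 with calcitriol, 6.23 with TGF-β1 and 10.32 with both, and HPGD averaged 8.95, 8.68, 7.01 and 7.54 in the same order.

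The second comparison asks what TGF-β1 alone does. TGFBI, an extracellular matrix protein named for its induction by TGF-β, rose 9.68-fold (log2 change 3.27 ± 0.14, SE, n = 2 per group, adjusted p = 0.000464). The integrin subunits ITGB6 and ITGB3 rose 4.01-fold and 3.51-fold (ITGB6 on 1 feature, with -0.0023 and 0.22 on others whose mean levels lay under background), the cytokine IL6 rose 3.97-fold, IGFBP3 rose 3.86-fold and the kinase SGK1 rose 3.70-fold. HPGD, which breaks down prostaglandins, fell by 1.94 ± 0.10 (adjusted p = 0.00105), and SPRY1, an inhibitor of receptor tyrosine kinase signalling, fell by 1.84 ± 0.10 (adjusted p = 0.00105). TBXAS1, the thromboxane synthase, fell by 1.88 and ANKRD22 fell by 1.82. In all, 145 genes changed, 82 higher and 63 lower, and 61 of them by at least 2-fold. Of the 145, 129 are protein-coding (71 higher, 58 lower). SERPINB3 and SERPINB4 are near-identical protease inhibitors that the array may not separate. SERPINB3 was lower (levels 6.49 and 4.51, adjusted p = 0.0247), with 1 of the 2 TGF-β1 arrays above background, so no fold is given. SERPINB4 was at background on both TGF-β1 arrays and at least 1.61-fold lower (5.43 and 3.55, adjusted p = 0.0232). SULT1B1, a sulfotransferase at background in control and above it on 1 of the 2 TGF-β1 arrays, was at least 1.03-fold higher (adjusted p = 0.0345). CYP24A1 stood at 6.23 against 5.49 in control (0.74 ± 0.35, adjusted p = 0.452) and VDR at 9.43 (-0.10, adjusted p = 0.757).

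The count of genes changed by TGF-β1 was 12 without either TGF-β1 array, 14 without control replicate B, 26 without control replicate A, 42 without either combination array and 48 without either calcitriol array. Among protein-coding genes alone 242 passed (127 higher, 115 lower), and after cyclic loess over these genes, chosen after seeing the data, 271 passed (177 higher, 94 lower).

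TGF-β1 shifted 11 of the 32 fixed lists, 7 up and 4 down, and 3 of them also passed with an estimated correlation. The list medians below stand against a median of -0.06 over protein-coding genes and 0.04 over pseudogenes. Those 3 were the TGF-β/SMAD targets, the extracellular matrix genes and the matrix proteases, each with an adjusted p = 0.0458 with an estimated correlation. Of 28 TGF-β/SMAD targets, 9 rose and 0 fell over all genes, and 14 rose when adjusted over the list alone (median 0.46, camera adjusted p = 3.07e-13). They include LTBP2 (1.19), PMEPA1 (1.19 ± 0.12, adjusted p = 0.0124), JUNB (1.12) and SMAD7, an inhibitor of the pathway (0.81 ± 0.13, adjusted p = 0.0466, with 0.49 on another feature that did not pass). Of 24 collagen and matrix genes, 6 rose, and 11 rose and 2 fell when adjusted over the list alone (median 0.34, camera adjusted p = 5.84e-07). The largest were the proteoglycan genes VCAN (1.36) and SPOCK1 (1.27) with COL5A1 (1.34) and fibronectin, FN1 (1.19). Of 21 matrix proteases and inhibitors, 2 rose, SERPINE2 (0.97) and MMP14 (0.81), and 8 rose when adjusted over the list alone (median 0.29, camera adjusted p = 5.84e-07). Of 24 mesenchymal genes, 4 rose, FN1, TPM1 (0.84), SNAI2 (0.72) and ITGA5 (0.63), and 8 rose and 1 fell when adjusted over the list alone (median 0.23, camera adjusted p = 1.86e-05, adjusted p = 0.0541 with an estimated correlation). Of 12 integrins, 3 rose, and 5 rose and 1 fell when adjusted over the list alone (median 0.17, camera adjusted p = 0.00315, adjusted p = 0.129 with an estimated correlation).

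Of 24 actin cytoskeleton genes, 2 rose with TGF-β1, RHOB (1.16) and TPM1, and 5 when adjusted over the list alone (median 0.19, camera adjusted p = 3.33e-07, adjusted p = 0.125 with an estimated correlation). Of 18 angiogenesis factors, 2 rose, NRP2 (0.81) and VEGFA (0.79), and 5 when adjusted over the list alone (median 0.05, camera adjusted p = 0.0371, adjusted p = 0.263 with an estimated correlation). The list of EGFR ligands and MAPK feedback genes was shifted down (median -0.36, camera adjusted p = 5.51e-06, adjusted p = 0.182 with an estimated correlation). Of its 23 members, 3 fell and 2 rose over all genes, and 13 fell and 2 rose when adjusted over the list alone. SPRY1 fell, as did EREG, an EGFR ligand that was at least 1.24-fold lower and at background, while the phosphatase DUSP1 (1.22) and the ligand HBEGF (0.86) rose. Of 15 prostaglandin pathway genes, HPGD and the receptor PTGFR (-0.78) fell and PTGS2, the inducible cyclooxygenase, rose (1.03). When adjusted over the list alone, 3 of them fell and 1 rose (median -0.18, camera adjusted p = 0.00658, adjusted p = 0.138 with an estimated correlation). In the NRF2 list of 20, SLC7A11, a cystine transporter, fell by 0.77, the single change over all genes and when adjusted over the list alone (median -0.14, camera adjusted p = 0.00353, adjusted p = 0.263 with an estimated correlation). The 32 proliferation genes were shifted down by a median of -0.16 with 0 single genes changed over all genes or when adjusted over the list alone in limma (camera adjusted p = 0.000274, adjusted p = 0.281 with an estimated correlation). After cyclic loess over protein-coding genes, chosen after seeing the data, the 4 lists shifted down by TGF-β1 stayed so. Their medians were then -0.31 (EGFR and MAPK), -0.12 (prostaglandin), -0.09 (NRF2) and -0.11 (proliferation). The camera adjusted p-values were 2.97e-05, 0.0236, 0.0222 and 0.004 in the same order.

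The epithelial list was not shifted by TGF-β1 (camera adjusted p = 0.212). Of its 29 members KRT7, a simple epithelial keratin, rose (0.70, with 0.10 on another feature that did not pass), and 2 rose and 2 fell when adjusted over the list alone. CDKN1A, a cell cycle inhibitor held by the growth arrest and the vitamin D receptor lists, rose by 1.09 ± 0.14 (adjusted p = 0.0245). STEAP4, a metalloreductase of the luminal prostate list, fell by 1.48 ± 0.10 (adjusted p = 0.0019). IL1B rose (0.94), STS, the steroid sulfatase, fell by 0.69, and FBP1, a gluconeogenic enzyme, fell by 0.83. The NF-κB list, with a median of -0.05, did not pass (camera adjusted p = 0.0749, adjusted p = 0.441 with an estimated correlation), and did after cyclic loess over protein-coding genes (adjusted p = 0.0236). Markers of other cell types did not shift, with camera adjusted p = 0.838 for fibroblasts, 0.651 for leukocytes and 0.75 for endothelium. The ribosomal (0.398) and housekeeping (0.432) lists did not shift either.

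**Figure D2:**
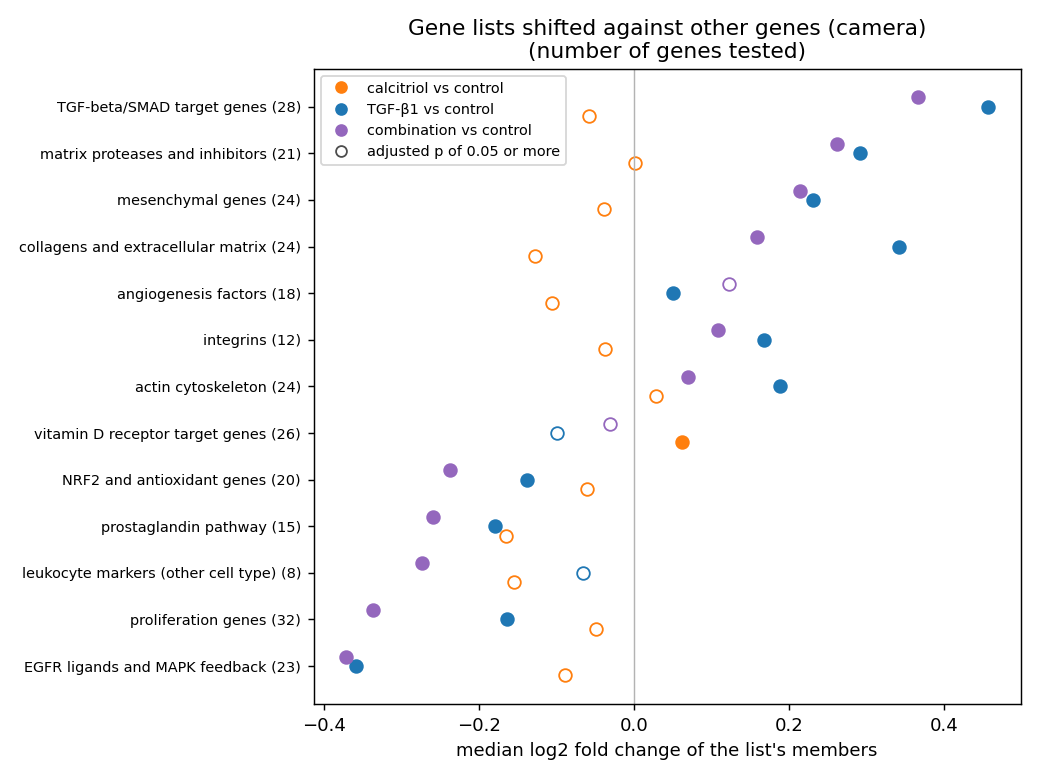
Median log2 fold change against control of each gene list that was shifted in at least 1 of the 3 treatments, with the number of genes tested; filled points have a camera adjusted p under 0.05. The TGF-β/SMAD targets had medians of 0.46 with TGF-β1 and 0.37 with the combination.

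The third comparison sets the combination against control. CYP24A1 rose 28.3-fold (log2 change 4.82 ± 0.35, SE, n = 2 per group, adjusted p = 0.00297), with levels of 10.93 and 9.71 in replicates A and B. TGFBI rose 9.10-fold (3.19 ± 0.14, adjusted p = 0.000383), IGFBP3 rose 5.42-fold (2.44 ± 0.11, adjusted p = 0.000383) and the hair keratin KRT34 rose 5.01-fold (2.33 ± 0.14, adjusted p = 0.00113). KRT34 also rose with TGF-β1 alone (1.77, adjusted p = 0.00399) and did not pass with calcitriol alone (1.23, adjusted p = 0.12). Its difference between the combination and TGF-β1 did not pass (0.56, adjusted p = 0.517). IL6 rose 4.36-fold, ITGB3 4.21-fold and ITGB6 4.15-fold, the last on 1 feature, with -0.28 on another whose mean level lay under background. TBXAS1 was lower (levels 6.90 and 4.85, with 1 of the 2 combination arrays above background, so no fold is given). The largest other falls were of SPRY1 (-1.78), ANKRD22 (-1.74) and APOBEC3G, a cytidine deaminase with close paralogs (-1.60). SERPINB3 and SERPINB4, at background on both combination arrays, were at least 3.18-fold and at least 1.53-fold lower. In all, 542 genes changed, 267 higher and 275 lower, of which 111 by at least 2-fold. Protein-coding genes made up 394 of them (150 higher, 244 lower). As a class, protein-coding genes had a median log2 change of -0.12, whereas the 5862 pseudogenes had 0.10, with 94 higher and 9 lower. Negative control features of the array had a median of 2.75 ± 0.078 in the combination and 2.61 ± 0.015 in control (SD, n = 2).

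The count of genes changed by the combination was 13 without combination replicate A, 15 without combination replicate B, 22 without control replicate B, 218 without control replicate A, 213 without either calcitriol array and 154 without either TGF-β1 array. Among protein-coding genes alone 931 passed (260 higher, 671 lower), and after cyclic loess over these genes, which moved their median from -0.119 to -0.004, 572 passed (371 higher, 201 lower), 459 of them shared with the 931.

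The combination shifted 11 lists, 6 up and 5 down, and 0 with an estimated correlation (lowest adjusted p = 0.184 with an estimated correlation) and 18 by fry, which does not compare a list with other genes. The list medians below stand against the median of -0.12 over protein-coding genes, and values after cyclic loess over protein-coding genes were chosen after seeing the data. Of 28 TGF-β/SMAD targets, 10 rose and 13 rose when adjusted over the list alone (median 0.37, or 0.48 after loess, camera adjusted p = 2.88e-07, adjusted p = 0.184 with an estimated correlation). JUNB (1.20), AMIGO2 (1.11), LTBP2 (1.04), SMAD7 (0.96 ± 0.13, adjusted p = 0.0187, with 0.48 on another feature that did not pass) and PMEPA1 (0.95 ± 0.12, adjusted p = 0.0152) were among them. Of 24 matrix genes, 6 rose and 1 fell, and 9 rose and 3 fell when adjusted over the list alone (median 0.16, or 0.28 after loess, camera adjusted p = 0.00438, adjusted p = 0.184 with an estimated correlation). FN1 (1.28) and SPOCK1 (1.24) rose and COL5A2 fell (-0.62). Of 21 matrix proteases and inhibitors, 4 rose, SERPINE2 (1.27), ADAMTS1 (0.79), TIMP1 (0.73) and PLAU (0.47), and 8 when adjusted over the list alone (median 0.26, or 0.38 after loess, camera adjusted p = 0.000228, adjusted p = 0.184 with an estimated correlation). Of 24 mesenchymal genes, 4 rose, among them TAGLN (0.71), and 7 rose and 1 fell when adjusted over the list alone (median 0.21, or 0.33 after loess, camera adjusted p = 0.00617, adjusted p = 0.184 with an estimated correlation). Of 12 integrins, 3 rose, with ITGAV (0.60) beside ITGB3 and ITGB6, and ITGB4 fell (-0.55). When adjusted over the list alone, 5 integrins rose and 1 fell (median 0.11, or 0.22 after loess, camera adjusted p = 0.0121, adjusted p = 0.203 with an estimated correlation). Of 24 actin cytoskeleton genes, 3 rose, RHOB (0.83), TPM1 (0.76) and CALD1 (0.72), and 4 when adjusted over the list alone (median 0.07, or 0.18 after loess, camera adjusted p = 0.00404, adjusted p = 0.26 with an estimated correlation).

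Proliferation genes were shifted down in the combination by a median of -0.34, or -0.22 after the same loess (camera adjusted p = 1.86e-06, adjusted p = 0.211 with an estimated correlation). In limma 0 of the 32 changed over all genes, and 18 fell and 1 rose when adjusted over the list alone. BIRC5 (-0.57, adjusted p = 0.051 over all genes), MCM7 (-0.49), AURKB (-0.47) and MCM3 (-0.46) had the lowest values. CCNE2 (0.34) was the one that rose over the list alone. Of 23 EGFR ligands and MAPK feedback genes, 4 fell and 2 rose over all genes, and 12 fell and 2 rose when adjusted over the list alone (median -0.37, or -0.25 after loess, camera adjusted p = 0.000247, adjusted p = 0.26 with an estimated correlation). SPRY1 and DUSP6 (-0.77) fell, and DUSP1 (1.30) and HBEGF (0.92) rose. In the prostaglandin list HPGD (-1.41) and PTGFR (-0.87) fell and PTGS2 (1.42) rose, and 4 fell and 1 rose when adjusted over the list alone (median -0.26, or -0.15 after loess, camera adjusted p = 0.00625, adjusted p = 0.184 with an estimated correlation). In the NRF2 list SLC7A11 fell by 1.01, the single change over all genes, and 3 fell when adjusted over the list alone (median -0.24, or -0.12 after loess, camera adjusted p = 0.00438, adjusted p = 0.26 with an estimated correlation). The 8 leukocyte markers were shifted down (median -0.27, camera adjusted p = 0.036, adjusted p = 0.299 with an estimated correlation), with 1 lower over all genes and when adjusted over the list alone. That gene, PTPRC, was above background on 1 control array and on neither combination array, and after loess the list did not pass (adjusted p = 0.115).

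The vitamin D receptor targets went both ways in the combination and were not shifted (camera adjusted p = 0.303). Over all genes 6 of the 26 rose, CYP24A1, IGFBP3, CDKN1A (1.08), EFL1 (0.91), CST6 (0.88) and DUSP10 (0.68), and 3 fell, HPGD, FBP1 (-0.89) and CLMN (-0.66). When adjusted over the list alone, 6 rose and 5 fell. MYC (-0.74) and WNT7B (-0.80) of the Wnt list fell, as did CA12 (-0.78) and NDRG1 (-0.74) of the hypoxia list, while VEGFA rose (0.69). STEAP4 fell by 1.09, and HOXB13, a prostate homeobox factor, fell by 0.60. The type II TGF-β receptor TGFBR2 fell (-0.57), whereas BMPR2 (0.84), SMURF2 (0.57) and INHBA (0.57) rose. The epithelial list was not shifted (camera adjusted p = 0.0883), with TJP1 (0.58, and 1.79 on another feature) and KRT7 (0.56, but -0.21 on another feature) higher and ELF3 (-0.63) lower. SULT1E1 passed the test (adjusted p = 0.0306) but lay under background in both groups. VDR stood at 9.17 (-0.36 ± 0.10, adjusted p = 0.0958). The growth arrest list (median 0.08, camera adjusted p = 0.0951, adjusted p = 0.278 with an estimated correlation) and the angiogenesis list (median 0.12, camera adjusted p = 0.0928, adjusted p = 0.31 with an estimated correlation) did not pass, and both did after loess (adjusted p = 0.0151 and 0.0266). The ribosomal list had a median of -0.19 (camera adjusted p = 0.0584), and the housekeeping list did not shift (adjusted p = 0.884).

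**Figure D3:**
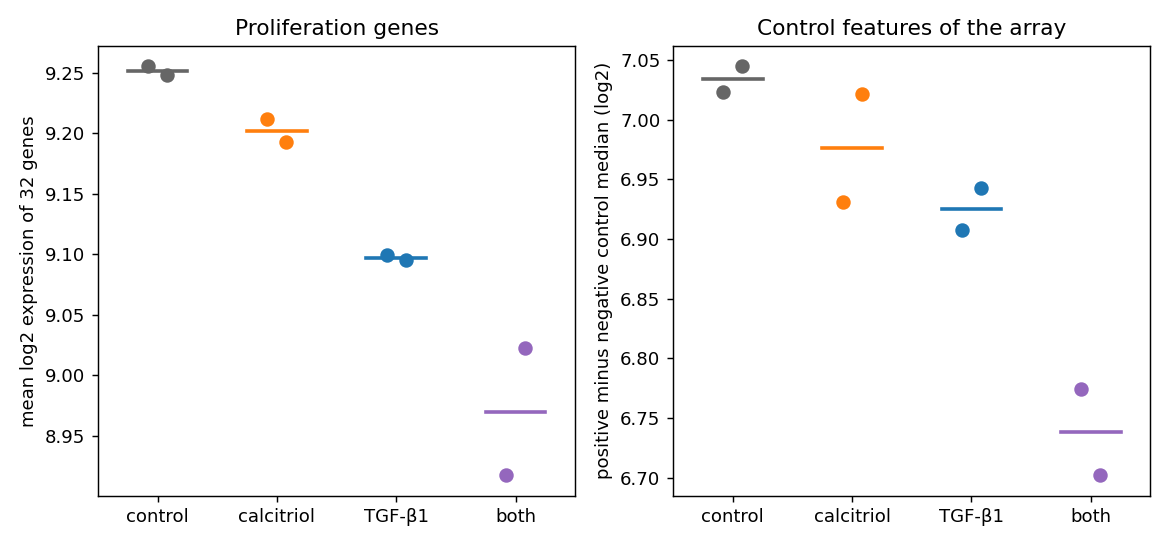
Left, mean log2 expression of the 32 proliferation genes in each array; right, the gap between the medians of the positive and the negative control features (log2). Points are arrays, bars are group means, and the gap averaged 7.03 in control and 6.74 in the combination.

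The fourth comparison asks whether TGF-β1 acts in cells that also receive calcitriol, by setting the combination against calcitriol alone. TGFBI rose 7.17-fold (log2 change 2.84 ± 0.14, SE, n = 2 per group, adjusted p = 0.00135), ITGB6 4.40-fold, IL6 3.71-fold and ITGB3 3.17-fold. NKILA, a long non-coding RNA that restrains NF-κB signalling, also rose (3.77-fold, adjusted p = 0.0381). The log2 change of NKILA depended on the calcitriol array kept, at 1.45 without calcitriol replicate B and 2.38 without replicate A. SPRY1 (-1.50), ANKRD22 (-1.44), APOBEC3G (-1.31), SH3TC2 (-1.24) and TBXAS1 (levels 6.22 and 4.85, with 1 of the 2 combination arrays above background) fell. The checks PMEPA1 (1.25 ± 0.12, adjusted p = 0.0115) and SMAD7 (0.84 ± 0.13, adjusted p = 0.0456) rose, and CYP24A1 (0.37, adjusted p = 0.664, or -0.24 without combination replicate A) and VDR (-0.06, adjusted p = 0.834) did not pass. In all, 140 genes changed, 94 higher and 46 lower, with 122 protein-coding, and 3517 had an unadjusted p under 0.05. The count was 0 without combination replicate A in limma, 4 without combination replicate B, 1 without either calcitriol array, 36 without either TGF-β1 array and 83 without either control array. Among protein-coding genes alone it was 189 (106 higher, 83 lower), and 207 (144 higher, 63 lower) after cyclic loess over them.

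In this comparison 11 lists were shifted, 8 up and 3 down, and 0 with an estimated correlation (lowest adjusted p = 0.118 with an estimated correlation) and 15 by fry, which does not compare a list with other genes. Of 28 TGF-β/SMAD targets 9 rose, and 15 rose and 2 fell when adjusted over the list alone (camera adjusted p = 4.85e-11, adjusted p = 0.118 with an estimated correlation). Of the matrix genes 4 rose, and 9 rose and 1 fell when adjusted over the list alone (camera adjusted p = 6.32e-05, adjusted p = 0.118 with an estimated correlation). Integrins (camera adjusted p = 0.00152), mesenchymal genes (0.00413) and matrix proteases (0.00304) were also shifted up, each with an adjusted p = 0.145 with an estimated correlation. When adjusted over the list alone, 5 integrins, 6 mesenchymal genes and 6 proteases rose and 1 of each fell, against 3, 3 and 1 that rose over all genes. The NF-κB list was shifted up (camera adjusted p = 0.0111, adjusted p = 0.331 with an estimated correlation), with IL6 and IL1B (0.93) higher over all genes and 4 members higher when adjusted over the list alone. The 32 proliferation genes were shifted down by a median of -0.24 (camera adjusted p = 1.73e-07, adjusted p = 0.173 with an estimated correlation), with 0 changed over all genes in limma and 11 lower when adjusted over the list alone. EGFR ligands and MAPK feedback genes were shifted down (camera adjusted p = 0.000343, adjusted p = 0.269 with an estimated correlation). In that list 2 rose and 2 fell over all genes, and 2 rose and 9 fell when adjusted over the list alone. The NRF2 list was shifted down (camera adjusted p = 0.00334, adjusted p = 0.269 with an estimated correlation), with SLC7A11 (-0.70) the single gene lower over all genes and when adjusted over the list alone. Protein-coding genes had a median of -0.06 in this comparison and pseudogenes 0.07. After cyclic loess over protein-coding genes the proliferation, EGFR and NRF2 lists stayed shifted down (medians -0.16, -0.19 and -0.12, camera adjusted p = 3.77e-05, 0.00126 and 0.0332). Angiogenesis factors were shifted up (camera adjusted p = 0.00393, adjusted p = 0.173 with an estimated correlation), with VEGFA (0.62) higher over all genes and 5 higher when adjusted over the list alone. Actin genes were shifted up as well (camera adjusted p = 0.0211, adjusted p = 0.331 with an estimated correlation), with 1 higher over all genes and 4 when adjusted over the list alone.

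The effect of TGF-β1 without calcitriol and with it was measured on separate arrays. Across 23854 genes, which are not independent replicates, the log2 changes correlated at r = 0.459 (Spearman's rho 0.384). Of the 145 and 140 genes changed, 89 changed in both, 57 higher and 32 lower and 0 in opposite directions, where independent lists would share 0.323 higher and 0.121 lower. The arrays are separate, but both contrasts come from 1 fit and use the same estimate of spread for each gene. Genes with a low estimate tend to pass in both, so the numbers for independent lists may be too low. Over all genes, 64.6% had the same sign in both. Of the 145 genes, 139 did, with a median ratio of log2 changes of 0.849, but these genes were selected for their change without calcitriol, which by itself favours a ratio under 1. TGFBI, ITGB6, IL6 and ITGB3 rose and SPRY1, TBXAS1 and ANKRD22 fell in both.

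**Figure D4:**
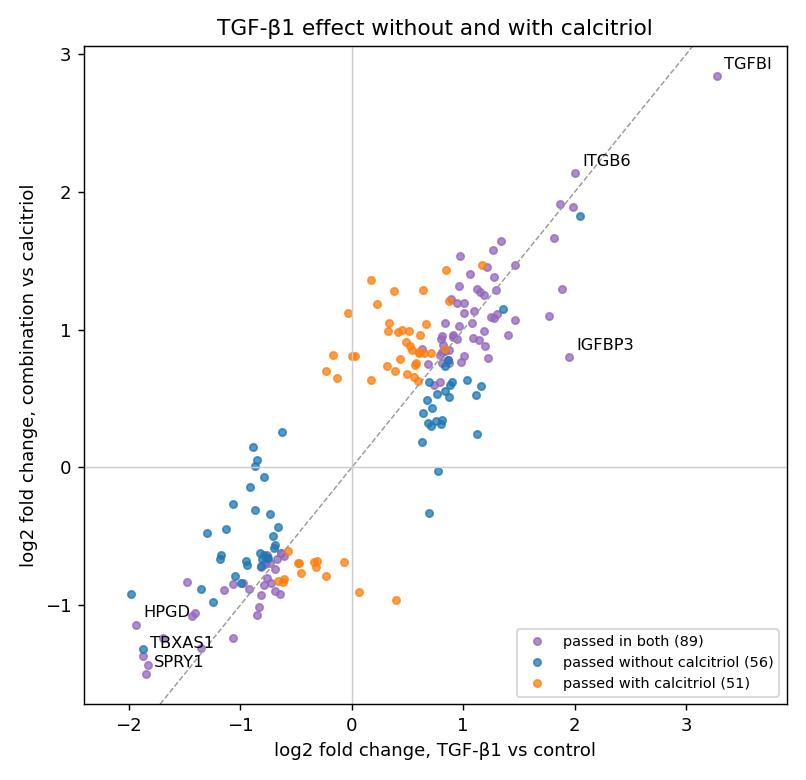
Log2 fold change of TGF-β1 against control (horizontal) and of the combination against calcitriol (vertical) for each gene changed in at least 1 of the 2 comparisons; the dashed line marks equal change. The 89 genes changed in both lie in the same direction, with TGFBI at 3.27 and 2.84.

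The fifth comparison asks what calcitriol adds in cells that receive TGF-β1, by setting the combination against TGF-β1 alone. CYP24A1 had the lowest p-value, at 10.32 against 6.23 (log2 change 4.09 ± 0.35, SE, n = 2 per group, adjusted p = 0.0935), and did not pass over all genes. In limma 0 genes changed, 2210 had an unadjusted p under 0.05 against 1192.7 by chance, and the settings tried gave 0 to 5. Without combination replicate B 1 gene passed. The next lowest p-values were those of EFL1 (1.07, adjusted p = 0.308), GPR78, an orphan receptor at background in the combination (levels 5.16 and 4.27, adjusted p = 0.308), LINC00592, under background in both groups, and the olfactory receptor OR5P2 (0.71, adjusted p = 0.346), none of which passed. VDR (-0.26, adjusted p = 0.537), SMAD7 (0.16, adjusted p = 0.714) and PMEPA1 (-0.24, adjusted p = 0.566) did not pass. The vitamin D receptor targets were shifted up (camera adjusted p = 0.0277, adjusted p = 0.731 with an estimated correlation). Of the 26, 0 changed over all genes in limma, and 4 rose when adjusted over the list alone: CYP24A1, EFL1, HPGD (0.52) and IGFBP3 (0.49). Proliferation genes were shifted down by a median of -0.13 (camera adjusted p = 0.0114, adjusted p = 0.731 with an estimated correlation), with 0 members changed over all genes or when adjusted over the list alone, and did not pass after cyclic loess over protein-coding genes (adjusted p = 0.143). The calcitriol effects without and with TGF-β1, on separate arrays, correlated at r = 0.230 across genes (Spearman's rho 0.224).

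The interaction asks whether the effects of the agents differ from adding up on the log2 scale. In limma 0 genes passed, 1229 had an unadjusted p under 0.05 against 1192.7 by chance, and the settings tried gave 0 to 2. The lowest adjusted p-values belonged to LINC00592 (0.385, under background in every group), IGFBP3 (interaction -1.14 ± 0.16, SE, n = 2 per group, adjusted p = 0.552), GPR78 (-0.97, adjusted p = 0.552), DNAAF19 (0.89, adjusted p = 0.552) and BBOF1 (adjusted p = 0.679, under background in every group but calcitriol). IGFBP3 levels were 9.88 in control, 11.51 with calcitriol, 11.82 with TGF-β1 and 12.32 with both. The interaction was -0.37 ± 0.50 for CYP24A1 (0.24 without combination replicate B), 0.04 ± 0.14 for VDR, 0.03 ± 0.18 for SMAD7 and 0.07 ± 0.17 for PMEPA1, each with an adjusted p of 0.998. No list was shifted (lowest adjusted p = 0.89 with an estimated correlation, 0 by camera and 0 by fry), and camera called 2 lists without combination replicate B.

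Comparisons against the same controls share chance values. TGF-β1 and the combination shared 126 changed genes, 74 higher and 52 lower and 0 opposite, where independent lists would share 0.918 and 0.726. Their changes correlated at r = 0.721 against a mean of 0.50 (0.484 to 0.516) in simulations with no effect, and their covariance was 0.0506 against 0.0124. Calcitriol and the combination shared both calcitriol genes (r = 0.571 against 0.50 with a range of 0.486 to 0.511, covariance 0.0333 against 0.0124). Calcitriol and TGF-β1 shared 1 gene, IGFBP3, where independent lists would share 0.00688. Their correlation of r = 0.514 lay within the simulated range of 0.486 to 0.517, and their covariance was 0.0240 against 0.0124 (highest simulated 0.0129). The simulations used the moderated spread pooled over all groups. The control arrays differed more (SD of their difference 0.281) than the replicates of the other groups (0.235 to 0.246). The simulated covariances may therefore be too low for each pair, and an excess over them does not by itself show a shared effect. The 2 controls cannot be split into sets of 2 arrays, so part of the overlaps and correlations may come from the shared controls. Part of the overlaps may also come from the estimate of spread that the tests of a gene share. With 1 control array in each comparison, a split chosen after seeing the data, the covariance was 0.0252 and 0.0365 for TGF-β1 and the combination, 0.00922 and 0.0180 for calcitriol and the combination, and 0.00549 and 0.00300 for calcitriol and TGF-β1 (r = 0.270 and 0.425, 0.116 and 0.231, 0.0855 and 0.0439), where a lone control adds noise that lowers r. Of the 542 genes changed by the combination, 415 passed in neither single treatment, which does not show that they differ between treatments, since 0 genes passed the interaction test or the comparison with TGF-β1.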

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

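The linear-scale and saturation tests of IGFBP3 and the loess over protein-coding genes were chosen after the results were seen.

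Over all genes 0 interactions passed in limma (lowest adjusted p 0.385, 1229 at an unadjusted p under 0.05, and 0 to 2 by other settings). The interactions of 5 genes passed only when adjusted over a list alone, which does not show that the effect of either agent differed with the other present. IGFBP3 had an interaction of -1.14 (adjusted p = 0.00264 over the list, 0.552 over all genes). HPGD had 0.80 (0.00811 and 0.679), with a TGF-β1 effect of -1.94 without calcitriol and -1.14 with it. STEAP4 had 0.65 (0.0284 and 0.769). EREG had 0.91 (0.0335 and 0.744) and PECAM1 had -0.89 (0.00995 and 0.679), and the levels of both lay near or under the background of 4.82.

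Features without a gene name in the probe table, outside the comparisons of genes, were higher against control in 13 cases with TGF-β1 and 57 with the combination, and in 4 cases with the combination against calcitriol, of 46837 tested. They were lower in 2, 4 and 0 cases, and 1 fell by 3.63 with calcitriol. The negative control features of the array had a median of 2.75 in the combination, above the 2.61 in control.

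More genes passed in the combination (542) than with TGF-β1 (145), while against control protein-coding genes had a median change of -0.12 and pseudogenes of 0.10 on the combination arrays, and their control features lay closer together. The gap in counts was small with only the groups compared (14 against 12). It held without the filter (134 against 38), with the stricter filter (1811 against 364), with trend and robust moderation (3072 against 762) and with the replicate block (213 against 43). Omitting 1 array narrowed, turned or kept the gap, depending on the array. Such fits leave a group with a single array, so their counts do not compare like with like. Cyclic loess over protein-coding genes lowered the coding count from 931 to 572, still above the 271 for TGF-β1 in the same setting, so a loss of contrast on these arrays may account for part of the count, and how much cannot be told apart from the treatment. If calcitriol shifts the same genes with and without TGF-β1, its effects on separate arrays should correlate. Across protein-coding genes r was 0.222, and 0.191 without CYP24A1 and IGFBP3. The first lay above the highest of 8 values built from replicate differences, which mirror each other in sign (-0.0937 to 0.0937). Those values hold no shift common to both arrays of a group. The control feature gap fell from 7.03 to 6.98 with calcitriol alone and from 6.93 to 6.74 with calcitriol beside TGF-β1. A loss of contrast left after loess could therefore also give a positive r. A small calcitriol effect spread over many genes stays a candidate explanation for part of the pattern. The correlation cannot tell it apart from the loss of contrast. That effect passed for 0 single genes in the combination against TGF-β1 in limma, with 2210 at an unadjusted p under 0.05 and 0 to 5 by other settings.

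The list of proliferation genes was shifted down in the combination (median -0.34, or -0.22 after loess over protein-coding genes), a call lost at an adjusted p = 0.211 with an estimated correlation, and of its 32 members 0 passed over all genes in limma and 18 fell when adjusted over the list alone. A general fall of protein-coding genes is argued against, as 0 of 10000 random lists matched on level had a median as low (random median -0.11), and so is a single array, as the median stayed at -0.27 or lower without any 1 of the 4 control and combination arrays. With TGF-β1 alone 1 of 10000 random lists was as low, so the list's median lay under that of most genes of its level there. The call of the list with TGF-β1 was also lost with an estimated correlation, and single members did not pass even over the list alone. Random lists hold unrelated genes, so their share does not measure how far genes that vary together spread between experiments. The combination against calcitriol shares no array with TGF-β1 against control. Its list median was -0.24, and 0 of 10000 random lists were as low. After loess over protein-coding genes the list passed in both contrasts (camera adjusted p = 0.004 for TGF-β1 and 3.77e-05 against calcitriol). The list thus lay lower with TGF-β1 both without and with calcitriol. Both calls were lost with an estimated correlation, so whether TGF-β1 is a source of the shift stays open. Whether calcitriol contributes cannot be told apart, since 36.4% of random lists were as low for calcitriol against control and 1.03% for the combination against TGF-β1. The design holds no measurement of growth, so slower growth was not tested.

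IGFBP3 rose less with both agents than the log2 effects would add to, by an interaction that did not pass over all genes (adjusted p = 0.552). The linear signal in the combination was 0.909 of the sum of control and both linear rises (95% interval 0.793 to 1.05), so simple addition of the rises is a candidate explanation. Full saturation at the TGF-β1 level is argued against, since the combination stood 0.49 above TGF-β1 (log2, unadjusted 95% interval 0.23 to 0.75). That difference passed when adjusted over the list alone and not over all genes. Partial saturation was not tested and stays open.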

How the results depend on the processing

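Cyclic loess, the analysis of protein-coding genes and the use of 1 control array in each comparison were chosen after seeing the data. The other alternatives were planned. Repeated quantile normalization, median centring, loess over all features, the mean of a gene's features and a 1.5-fold minimum kept every count of changed genes within 1.5 times of its value. Counts follow in the order calcitriol, TGF-β1 and combination against control, then combination against calcitriol; the cause of a change was not tested except where fewer arrays or genes enter. Without the filter, with more genes in the adjustment, TGF-β1 gave 38, the combination 134 and the fourth comparison 56. With the stricter filter counts were 5, 364, 1811 and 304, and 1 for the combination against TGF-β1. Each feature on its own gave 1 (a fall of an unnamed feature), 36, 127 and 11. Moderation with trend and robust gave 18, 762, 3072 and 1059, with 5 against TGF-β1 and 2 for the interaction. Of the 2 genes changed by calcitriol in the main fit, only 1 was among those 18, so the other lost its call. Array weights gave 294 for the combination. Fits of the compared groups alone, with 2 residual degrees of freedom, gave 1, 12, 14 and 2. An adjusted p under 0.1 gave 307 for TGF-β1, 2083 for the combination, 263 against calcitriol and 1 against TGF-β1. Unadjusted p under 0.05 gave 1752, 3003, 5686 and 3517, with 2210 against TGF-β1 and 1229 for the interaction. Protein-coding genes alone gave 242 for TGF-β1 and 931 for the combination, and after loess over them TGF-β1 had 271.

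Arrays with the same replicate letter showed no shared deviation (correlations of -0.08 to 0.08 over 6 pairs, 0 over 0.1). With the replicate block, which leaves 3 residual degrees of freedom, counts were 0 for calcitriol, 43, 213 and 66, and 1 list for the combination against TGF-β1; 47 of 117 named calls were lost.

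Shifted lists with an estimated correlation numbered 0, 3, 0 and 0, and 0 against TGF-β1. Fry, which does not compare a list with other genes, gave 2 for calcitriol, 18 for the combination and 1 against TGF-β1. Without the filter, and after loess over protein-coding genes, 1 list passed against TGF-β1.

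Leaving out 1 array lowers the residual degrees of freedom, and the lone array left in a group is assumed to vary like the other groups. Changed genes then ranged over 0 to 2, 12 to 48, 13 to 218 and 0 to 83, with 0 to 1 against TGF-β1 and 0 to 0 for the interaction. Shifted lists ranged over 0 to 2, 9 to 12, 10 to 12 and 10 to 12, with 0 to 4 against TGF-β1 and 0 to 2 for the interaction. Of 936 values of named calls, 554 lost the call and 0 turned.

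Directions turned in called values only on another feature of the gene: ITGB6 gave -0.0023 (TGF-β1), -0.28 (combination) and -0.14 (against calcitriol) on a feature with a mean level of 3.20, under background, and KRT7 gave -0.21 (combination). Uncalled values turned too. With 1 control array in each comparison, also chosen after seeing the data, the 3 correlations between treatments fell both ways. SMAD7 with calcitriol was -0.079 for the mean of features and -0.28 on the other feature, and -0.020 there against TGF-β1. VDR against calcitriol was 0.023 after loess over protein-coding genes. With 1 array left out, CYP24A1 against calcitriol ranged from -0.24 (without combination replicate A) to 0.98 and VDR from -0.12 to 0.0061 (without combination replicate A). Interactions ranged from -0.98 to 0.24 for CYP24A1, -0.022 to 0.10 for VDR and -0.082 to 0.15 for SMAD7 (highest, lowest and lowest without combination replicate B), and from -0.064 (without TGF-β1 replicate A) to 0.20 for PMEPA1.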

Other observations

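Genes outside the fixed lists and the naming rule, chosen after their values were seen, changed against control with TGF-β1, with the combination or with both. The value given for the combination holds the effect of calcitriol too. The transcriptional repressor PRDM1 rose by 1.46 ± 0.17 with TGF-β1 and by 1.70 ± 0.17 with the combination (limma, SE, n = 2 per group, adjusted p = 0.0208 and 0.00723). The growth factor FGF5 rose by 1.40 and 1.57 and the decoy receptor IL13RA2 by 0.91 and 1.52. The immune checkpoint ligand PDCD1LG2 rose by 0.87 and 0.82. CD274, another such ligand, rose in the combination (0.86, adjusted p = 0.0283) and passed neither with calcitriol (0.76, adjusted p = 0.445) nor with TGF-β1 (0.57, adjusted p = 0.149). The secretory genes AGR2 (-1.15 and -1.33) and MUC5B (-1.05 and -1.26) fell, as did HAS3, a hyaluronan synthase (-1.41 and -1.28), RDH10, which makes retinal (-1.43 and -1.30), and CCNA1 (-1.69 and -1.58). The chorionic gonadotropin genes CGB1, CGB2 and CGB8 rose by 1.15, 1.09 and 1.28 with TGF-β1 and are near-identical copies, so their separate values are uncertain. CGB7, also tested, passed neither with TGF-β1 (0.53, adjusted p = 0.158) nor with the combination (0.54, adjusted p = 0.0705).

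Families of genes with a shared symbol stem were tested by Fisher's exact test, 783 families per comparison, after the values were seen. With TGF-β1, 3 of 8 APOBEC genes fell, APOBEC3C (-0.63), APOBEC3D (-0.70) and APOBEC3G (-1.35), with p = 1.2e-05 by Fisher's exact test and adjusted p = 0.00943. These are close paralogs. The combination also lowered 3 (adjusted p = 0.157). In the combination 35 of 650 RNU genes, copies of small nuclear RNAs, were higher and 0 lower (adjusted p = 0.00203 against all genes). Pseudogenes as a class moved the same way in that comparison (median 0.10, 94 higher and 9 lower, against a median of -0.12 for protein-coding genes), as did the negative control features (2.61 in control and 2.75 in the combination), and the RNU genes were not tested against that class. In the same comparison 3 of 5 tested symbols with the stem BMPR changed, 2 higher and 1 lower (adjusted p = 0.0441). Families were formed from the symbol alone, so this one may hold pseudogenes, which rose as a class here. The result is therefore not one on the BMP receptors as such.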
